A study of Drosophila melanogaster with 4 samples.

How the data were processed

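RNA from fly heads was measured in 4 libraries, grouped by their titles and genotype labels into 2 control (w1118) and 2 MJDtr-78Q libraries. Per the labels' protocols, total RNA was selected for poly(A) and made into stranded libraries with the Illumina TruSeq Stranded mRNA LT kit, and per the series' design text sequencing used an Illumina HiSeq instrument. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.2.1, TopHat2 2.0.10, Bowtie and HTSeq 0.6.1, without giving their roles. The genome build and annotation release are not given in the sources used here. Coordinates are printed as the deposited table gives them; 84 genes have a damaged locus entry and 254 lie on heterochromatic or unplaced arms.

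The deposited values are log2 of a count plus 1 for 15682 genes, as read from the values: the lowest above 0 are logs of small whole numbers, or means of 2 such logs. The sorted values of the 2 libraries of a group nearly coincide, while medians differ between groups by 1.27, so the table had been quantile normalized within each group and not between them, a step no label records. As deposited, the MJDtr-78Q libraries therefore lie below the control libraries by a median of -1.23 over the tested genes, a difference that mixes sequencing depth with expression. Back-transformed totals were 7147867 and 7147717 in control and 3111583 and 3111393 in MJDtr-78Q libraries, made equal within a group by the normalization, with 4179 and 4756 genes at 0 in control and 5069 and 5151 in MJDtr-78Q. The order of distinct values gave replicate 1 a depth of 1.85 times that of replicate 2 in control and 1.35 times in MJDtr-78Q. Whole reads per gene cannot be recovered from averaged log values, so counting error per gene is unknown and no interval based on counts is given.

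The design written before the data were examined was a limma model of log2(value + 1) on the authors' own scaling. Because the file holds log2 values already and the deposited scaling differs between groups, the 4 libraries were instead quantile normalized together, which had been listed as an alternative, and the deposited scaling became an alternative chosen after seeing the data. Genes with a mean of at least 10, after back-transformation, were kept, which left 9049. The groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(count + 1) scale, which understates changes of low genes. The labels do not say that the libraries came from separate cultures or animals. The p-values of single genes therefore measure only the spread between these samples, which may be technical.

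Gene symbols came from a reference table by gene ID: 15002 IDs matched and 680 did not. Exonic lengths came from an Ensembl annotation by gene ID, for 8641 of the tested genes (95.5%); none of its coordinates was used. For 43 gene lists fixed before the data were examined, camera was run with a preset correlation of 0.01 and then with an estimated correlation, and fry was run as a test of whether members move one way. With the preset correlation camera sets members against all other genes and counts genes as its units. Those p-values therefore do not measure the spread between libraries. With an estimated correlation its degrees of freedom come from the 4 libraries, so few lists could pass. At least 3 tested members were required, which left 40 lists; CrebA alone had 1 tested member, digestive serine proteases had 0 and chorion and vitelline membrane genes 2. Of the 9 COPII entries, 8 were in the table.

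Genes were named by a rule fixed beforehand: the 10 largest rises and 10 largest falls past the adjusted threshold with a mean of at least 50 and non-overlapping groups, which gave none, then up to 4 members of each list by increasing p, then CrebA, w and all tested COPII genes. Genes named after their values were seen are said to be so. Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, TMM and upper-quartile scaling, a robust variance prior, no intensity trend, the replicate number as a block, each library left out in turn, and the added ones. In the length correction a loess trend (span 0.5) on log2 exonic length was removed from each library.

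The steps were tested on 10 sets of simulated counts for this comparison, 1 set having given recoveries that moved with small changes of the simulated depth, each with 9030 to 9063 tested genes, or 8636 to 8667 with a length, 100 genes changed 2-fold and 100 changed 4-fold. Without a length trend a mean of 67.4 of the 2-fold and 97.9 of the 4-fold genes were recovered, with a mean of 6.0 unchanged genes called. With the length trend of these libraries, 0.30 and 48.4 were recovered (0 to 82 of the 4-fold genes over the 10 sets), and after length correction 66.5 and 97.5, with a mean of 7.2 unchanged genes called. Every simulated gene had the same assumed dispersion, 0.02, and the simulated trend was a straight line on log2 length. Length correction removes such a trend by construction, so its recovery says nothing of other differences between these libraries.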

Results

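Poly(A) RNA from the heads of Drosophila melanogaster was sequenced from 4 libraries, 2 of control flies of the w1118 strain and 2 of flies expressing MJDtr-78Q. MJDtr-78Q is a truncated form of the human MJD protein (ataxin-3) with an expanded polyglutamine tract, a toxic protein used to model Machado-Joseph disease. The comparison asks which head transcripts differ when this protein is present. The series title concerns Golgi outposts, the Golgi fragments found in dendrites, so genes of the secretory pathway were examined as a fixed group. The deposited table lists 15682 genes, of which 9049 were expressed highly enough to test. Its log2 values add up, after back-transformation, to 7147867 and 7147717 counts in the control libraries and 3111583 and 3111393 in the MJDtr-78Q libraries, a ratio of 2.30. All differences below are log2 values, MJDtr-78Q minus control, after quantile normalization over the 4 libraries, with n = 2 per group.

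**Figure D1:**
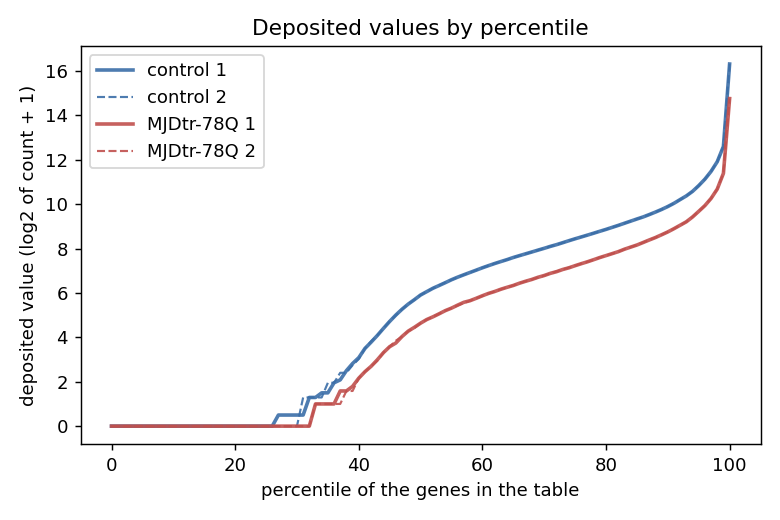
Deposited values, as log2 of the count plus 1, at each percentile of the 15682 genes, with a line per library (solid for replicate 1, dashed for replicate 2). The replicate lines of a group nearly coincide, and the medians are 5.91 in control and 4.64 in MJDtr-78Q libraries.

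The white gene w (FBgn0003996, X, positions 2684631 to 2690499 in the deposited table's coordinates), needed for eye colour and disrupted in w1118, was at 6.07 and 6.24 in control and at 6.55 and 6.92 in MJDtr-78Q libraries after quantile normalization. Its difference was 0.58 (SE 0.26), or -0.68 in the deposited values with no scaling between groups, and did not pass the test (limma adjusted p = 0.948). The human transgene was not analysed here, so the labels were not checked against its own level.

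By camera with a preset correlation, the proteasome genes were higher together in MJDtr-78Q heads. Photoreceptor genes, heat-inducible heat shock genes and several chemosensory genes were lower by the same test. None of these lists passed camera with an estimated correlation. It gave adjusted p = 0.737 for proteasome and photoreceptor genes, 0.809 for heat-inducible heat shock genes and 0.895 for both chemosensory lists. That test has few degrees of freedom with 4 libraries, so its failure decides little. The 2 chemosensory lists share genes. Without MJDtr-78Q library 1 both chemosensory calls were lost. Proteasome transcripts had a median difference of 0.88, or 1.84 times the control level. The photoreceptor channel gene trpl was 8.18 times lower, and the small heat shock gene Hsp27 was 6.57 times lower. COPII coat genes, which drive vesicle export from the endoplasmic reticulum (ER), had a median of 0.11 and did not pass the test.

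No single gene passed the test over all 9049 genes (limma, lowest adjusted p = 0.512). With the replicate number as a block in the same model, 387 genes passed, 229 higher and 158 lower. The labels do not say that equal numbers share a batch, so counts over all genes are from the fit without the block unless said otherwise. Counts adjusted over a list alone are too, and the block raised many of them: to 29 of 31 proteasome, 17 of 35 phototransduction, 9 of 16 heat-inducible, 19 of 41 cuticle, 3 of 20 muscle, 2 of 11 hemocyte, 12 of 26 odorant-binding and 8 of 17 organ marker genes, 7 of 19 UDP-glycosyltransferases, 4 of 17 clock, 3 of 12 sex-specific and 18 of 64 cytochrome P450 genes, while ribosomal genes stayed at 0 of 77 and COPII genes at 0 of 8. Other counts with the block were 8 of 19 fat body, 6 of 21 insulin and feeding and 5 of 27 immune effector genes. Apoptosis and JNK genes had 4 of 22 and antimicrobial peptides 3 of 13. Constitutive chaperones, unfolded protein response, neurotransmitter and glial marker genes had 1 each. At an unadjusted p under 0.05 there were 532 genes, 313 higher and 219 lower, where chance would give 452. Over the tested genes Pearson's r was 0.9745 between the controls and 0.910 between the MJDtr-78Q libraries. MJDtr-78Q library 2 was closer to the controls (r = 0.952 and 0.953) than to its own replicate, and MJDtr-78Q library 1 had r = 0.949 and 0.899 with control libraries 1 and 2. Both MJDtr-78Q libraries lay above both controls, or both below, for 2669 genes (29.5%, against 33.3% by chance), and 467 of these differed at least 2-fold, 279 higher and 188 lower. Of the 40 gene lists tested, 12 passed camera with a preset correlation of 0.01, 4 higher and 8 lower. None of them passed with an estimated correlation (lowest adjusted p = 0.737), and fry called 1 list. With 4 libraries the estimated-correlation test has few degrees of freedom, so this failure does not decide whether correlated members explain the calls. For phototransduction the estimate was 0.0056, below the preset 0.01, yet camera's unadjusted p went from 2.1e-10 to 0.021. Clock (-0.019) and sex-specific genes (-0.077) were below the preset too. The other called lists lay above it, from 0.030 for muscle markers to 0.993 for ribosomal genes. Among them were proteasome (0.666), heat-inducible (0.487), odorant-binding (0.651) and organ marker genes (0.595). For such lists the preset assumes far less correlation than was estimated, so those p-values may be too small. The plot of list members shows the gene lists, and the plot of selected genes gives values in each library.

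**Figure D2:**
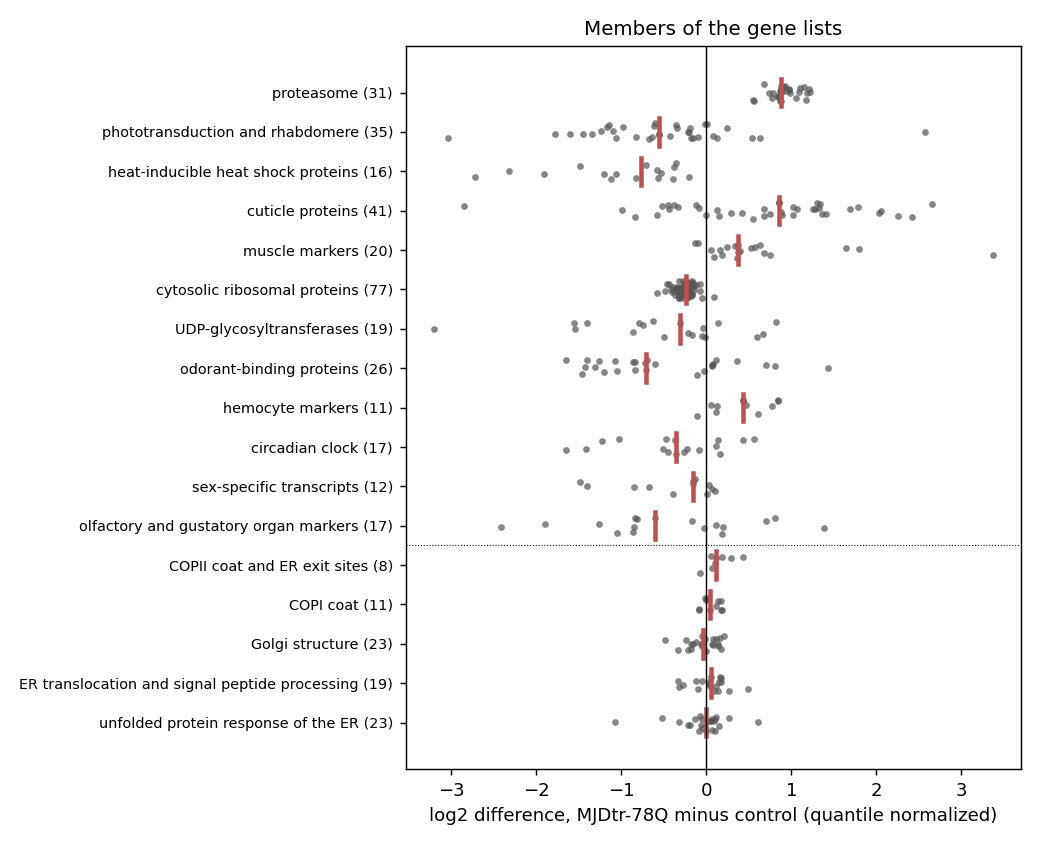
Log2 difference (MJDtr-78Q minus control) of every tested member of each gene list, with one point per gene and a red line at the list median; the number of members is in parentheses. Lists above the dotted line passed camera with the preset correlation. The 31 proteasome genes all lie above 0, and the 8 COPII genes lie close to 0.

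All 31 tested genes of the proteasome, which degrades ubiquitin-tagged proteins, were above 0, with quartiles of 0.85 and 1.02. Among the 31, 17 genes rose when p was adjusted over the list alone, 14 did not pass, and 0 passed over all genes. The lid subunit gene Rpn11 (FBgn0028694, 2L, positions 5058403 to 5059790), which encodes a deubiquitinase, was 9.48 ± 0.47 in control and 10.69 ± 0.07 in MJDtr-78Q heads (SD, n = 2 each), a difference of 1.21 (SE 0.31). The lid genes Rpn3, Rpn8 and Rpn7 differed by 1.19 (SE 0.29), 1.18 (SE 0.30) and 1.09 (SE 0.29). Each of these 4 genes had an adjusted p = 0.0455 over the list alone. The list passed camera at adjusted p = 1.5e-26, with adjusted p = 0.737 with an estimated correlation.

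Genes of phototransduction and of the rhabdomere, the light-sensing organelle of the photoreceptor, had a median of -0.55 over 35 members, of which 28 were below 0. Adjusted over the list alone, 8 fell, 1 rose and 26 did not pass; 0 passed over all genes. The gene trpl (FBgn0005614, 2R, positions 5641201 to 5653023), which encodes a light-activated cation channel, was 12.62 ± 0.18 in control and 9.59 ± 0.05 in MJDtr-78Q heads (SD, n = 2 each). Its difference of -3.03 (SE 0.23) had an adjusted p = 0.00198 over the list alone and an adjusted p = 0.512 over all genes. The ultraviolet opsin gene Rh4 fell by 1.45 (SE 0.23) and the arrestin gene Arr2 by 1.34 (SE 0.22), both with adjusted p = 0.0175 over the list alone. The member that rose was ninaD, a scavenger receptor gene needed for carotenoid uptake, by 2.57 (SE 0.31). Of genes singled out after their values were seen, the main opsin ninaE differed by -1.09 (SE 0.20), whereas the channel gene trp differed by 0.24 (SE 0.27) and ninaC, which encodes a photoreceptor myosin, by -0.01 (SE 0.44), the last of which turned to above 0 with TMM scaling. With a library left out ninaC ran from -0.60 without MJDtr-78Q library 1 to 0.59 without MJDtr-78Q library 2 (0.17 without control library 1 and -0.22 without control library 2). In the same way trp ran from 0.0041 without MJDtr-78Q library 1 to 0.46 without MJDtr-78Q library 2 (0.42 without control library 1 and 0.09 without control library 2). The list passed camera at adjusted p = 2.8e-09, with adjusted p = 0.737 with an estimated correlation.

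Heat-inducible heat shock genes, most of which encode stress-induced chaperones or co-chaperones, had a median of -0.77, and all 16 members were below 0. The list as fixed also names the noncoding RNA Hsromega. Adjusted over the list alone, 3 fell and 13 did not pass; 0 passed over all genes. Hsp27 (FBgn0001226, 3L, positions 9377162 to 9378382) was 8.93 ± 0.74 in control and 6.21 ± 0.54 in MJDtr-78Q heads (SD, n = 2 each), a difference of -2.72 (SE 0.47). Hsp68 differed by -2.31 (SE 0.50) and starvin (stv), which encodes a BAG-domain co-chaperone, by -1.06 (SE 0.24), both with adjusted p = 0.04 over the list alone. Hsp26 differed by -1.91 (SE 0.52) and did not pass (adjusted p = 0.0623 over the list alone). The Hsp70 copies in the list are nearly identical in sequence, so their separate values are uncertain. The list passed camera at adjusted p = 2.8e-09, with adjusted p = 0.809 with an estimated correlation. With no scaling between groups the call was lost (adjusted p = 0.0665), while the median relative to all tested genes was -0.78. Constitutive chaperones, by contrast, had a median of -0.11 over 19 members (mean 0.08) and did not pass (camera adjusted p = 0.394), with 0 members past the threshold adjusted over the list alone or over all genes. The member with the lowest p, Hsc70-2, was at 0.90 and 0.00 in control and at 4.36 and 4.73 in MJDtr-78Q libraries, a difference of 4.10 (SE 0.76) with adjusted p = 0.0627 over the list alone.

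**Figure D3:**
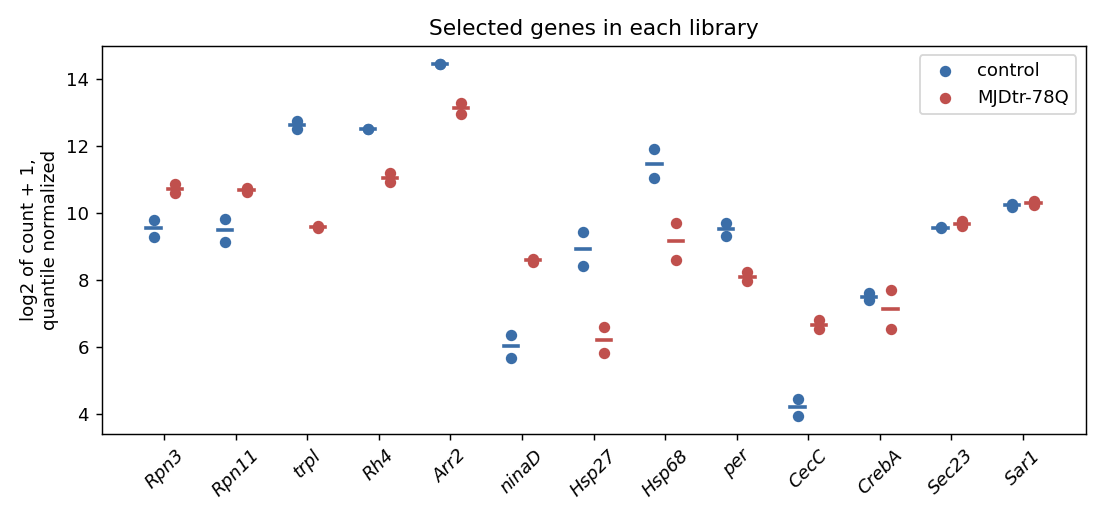
Quantile-normalized values (log2 of count plus 1) of 13 genes in each library, with one point per library and a bar at the mean of the 2 libraries of a group. The trpl values are 12.75 and 12.50 in control and 9.63 and 9.56 in MJDtr-78Q libraries, while Sec23 and Sar1 are nearly level.

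Lists of the early secretory pathway had small medians and gave no call. The 8 tested COPII genes had a median of 0.11, 7 of them above 0, and 0 passed adjusted over the list alone or over all genes. The inner coat gene Sec23 (FBgn0262125, 3R, positions 1474786 to 1478351) was 9.57 ± 0.02 in control and 9.69 ± 0.12 in MJDtr-78Q heads (SD, n = 2 each), a difference of 0.12 with a 95% interval of -0.47 to 0.70. The GTPase gene Sar1, which starts coat assembly, differed by 0.07 (SE 0.22). The cargo-binding coat genes Sec24AB and Sec24CD differed by 0.18 (SE 0.25) and 0.29 (SE 0.25), and the outer coat genes Sec13 and Sec31 by -0.07 (SE 0.26) and 0.10 (SE 0.27). The scaffold gene Sec16 differed by 0.44 (SE 0.48). CG9175, the Sec12 homologue, differed by 0.06 (SE 0.24), which turned to below 0 with upper-quartile scaling. The 95% interval of Sec16, -0.81 to 1.68, covers a 2-fold rise, so a rise of that size was not excluded. Intervals of the other COPII genes stayed short of 2-fold, that of Sec24CD running up to 0.95. Several signs turned with a library left out: without MJDtr-78Q library 1 the differences were -0.20 for Sec16, -0.15 for Sec31, -0.09 for CG9175, -0.00075 for Sec24AB and 0.08 for Sec13, Sec13 was at 0.08 without control library 2 as well, and Sec16 was at 0.23 without control library 2 and 1.07 without MJDtr-78Q library 2. Sec23, Sar1 and Sec24CD stayed above 0, from 0.04 to 0.20, 0.01 to 0.13 and 0.10 to 0.48. Relative to all tested genes the list's median was 0.13 with all 4 libraries, 0.03 without MJDtr-78Q library 1 and 0.32 without MJDtr-78Q library 2. The list did not pass (camera adjusted p = 0.276; adjusted p = 0.895 with an estimated correlation).

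CrebA (FBgn0004396, 3L, positions 15528513 to 15546314), a transcription factor that activates secretory pathway genes, was 7.50 ± 0.15 in control and 7.13 ± 0.82 in MJDtr-78Q heads (SD, n = 2 each). Its difference of -0.37 (SE 0.43) was smaller than the gap between the 2 MJDtr-78Q libraries, which were at 7.70 and 6.55 (limma adjusted p = 1). The 95% interval, -1.49 to 0.75, covers a 2-fold fall, so a fall of that size was not excluded. The difference was 0.20 without MJDtr-78Q library 2 and -0.94 without MJDtr-78Q library 1.

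Other secretory lists gave no call, with 0 members past the threshold adjusted over each list alone or over all genes. COPI coat genes, which return vesicles to the ER, had a median of 0.05 (11 genes, camera adjusted p = 0.547). The Golgi structure list had a median of -0.04 (23 genes, camera adjusted p = 0.868). Its members are not all structural. They include eIF3m, a translation initiation factor gene, at -0.48 (SE 0.44), and the enzyme gene Tpst, at 0.21 (SE 0.27). Genes of ER translocation and signal peptide processing had a median of 0.05 (19 genes, camera adjusted p = 0.407). The p24 cargo receptors, TRAPP and ER-Golgi SNARE genes had a median of -0.03 (23 genes, adjusted p = 0.948, where camera's direction was up), and relative to all tested genes it turned to above 0 with TMM and upper-quartile scaling. Genes of the unfolded protein response of the ER had a median of -0.0035 (23 genes, adjusted p = 0.948). Within that list the lectin chaperone gene Cnx99A differed by -1.08 (SE 0.31) and the thioredoxin-like prtp by 0.60 (SE 0.23), neither of which passed (adjusted p = 0.42 and adjusted p = 0.533 over the list alone).

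Cuticle, muscle and hemocyte genes were higher as groups by camera with the preset correlation (adjusted p = 1.2e-07, 5.7e-06 and 0.00256) but did not pass with an estimated correlation (adjusted p = 0.737, 0.737 and 0.895). Adjusted over each list alone, 0 of 41 cuticle, 1 of 20 muscle and 0 of 11 hemocyte genes passed, and 0 passed over all genes. Cuticle proteins, which form the exoskeleton, had a median of 0.85 over 41 members, 30 of them above 0; at unadjusted p under 0.05, 15 were higher and 1 was lower. Muscle markers had a median of 0.37 over 20 members, 18 of them above 0, and hemocyte (blood cell) markers one of 0.43 over 11 members, 10 of them above 0. Among cuticle genes, Cpr47Ef and Cpr92F differed by 1.07 (SE 0.23) and 1.34 (SE 0.30), while the neighbouring Ccp84Ad and Ccp84Ag went opposite ways, by 2.26 (SE 0.52) and -2.85 (SE 0.48). The muscle actin gene Act79B rose by 1.79 (SE 0.31), with adjusted p = 0.0488 over the list alone. Another actin gene, Act88F, differed by 1.64 (SE 0.44), and the troponin C gene TpnC47D by 3.37 (SE 0.76). The collagen gene vkg and the phagocytic receptor gene eater differed by 0.84 (SE 0.40) and 0.77 (SE 0.28), and vkg by 0.36 without MJDtr-78Q library 1 and 1.33 without MJDtr-78Q library 2. With no filter on low values the cuticle median relative to all tested genes was 0.58, against 0.88. The hemocyte call was lost without control library 2 (adjusted p = 0.114) and without MJDtr-78Q library 1 (adjusted p = 0.0608), with a median relative to all tested genes from 0.21 without control 2 to 0.77 without control 1 (0.28 without MJDtr-78Q library 1). Length correction took that median from 0.46 to 0.24, and the list still passed (adjusted p = 0.00535).

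Odorant-binding protein genes and olfactory and gustatory organ markers were lower by camera with the preset correlation (adjusted p = 0.00161 and 0.0177) but did not pass with an estimated correlation (adjusted p = 0.895 for each). Their medians were -0.71 over 26 members, 8 of them above 0, and -0.61 over 17 members, 6 of them above 0. The organ list itself holds odorant-binding genes, so the 2 calls rest partly on the same genes. The ionotropic co-receptor genes Ir25a and Ir76b fell by 1.89 (SE 0.35) and 2.41 (SE 0.51), with adjusted p = 0.0478 over the list alone. Obp99b, Obp57a and Obp56g differed by -1.40 (SE 0.28), -1.31 (SE 0.33) and -1.65 (SE 0.46), whereas Obp83g was higher, by 1.44 (SE 0.25). Obp99b is also in the fat body and sex-specific lists, so its fall is not particular to chemosensory genes. Adjusted over each list alone, 0 odorant-binding genes and 2 organ markers passed, and 0 over all genes. Both calls were lost without MJDtr-78Q library 1 (adjusted p = 0.599 and 0.831), and that of the organ markers also without control library 1 (adjusted p = 0.0758). Relative to all tested genes the medians ran from -1.16 and -0.93 without MJDtr-78Q library 2 to -0.16 and -0.08 without MJDtr-78Q library 1, with -0.36 and -0.29 without control library 2.

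UDP-glycosyltransferases, which conjugate small lipophilic molecules, had a median of -0.31 over 19 members. Adjusted over the list alone, 5 fell and 14 did not pass; 0 passed over all genes. Ugt36E1 fell by 1.55 (SE 0.24) and Ugt37A3 by 1.55 (SE 0.35). Camera gave adjusted p = 0.00161, with adjusted p = 0.885 with an estimated correlation, and the call was lost without MJDtr-78Q library 1 (adjusted p = 0.105). Relative to all tested genes the median was -0.58 without MJDtr-78Q library 2, -0.18 without control library 2 and -0.15 without MJDtr-78Q library 1, against -0.29 with all 4 libraries. It was -0.15 with no filter on low values and -0.18 at a mean of at least 50.

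Circadian clock genes had a median of -0.35 over 17 members, and 0 passed adjusted over the list alone or over all genes. The clock gene period (per) was 9.52 ± 0.28 in control and 8.10 ± 0.19 in MJDtr-78Q heads (SD, n = 2 each), a difference of -1.42 (SE 0.27), with adjusted p = 0.0571 over the list alone. The clock-controlled genes Slob, takeout (to) and Achl differed by -1.03 (SE 0.28), -1.23 (SE 0.35) and -1.64 (SE 0.56), and Achl by -0.85 without MJDtr-78Q library 2. Camera gave adjusted p = 0.00296, with adjusted p = 0.737 with an estimated correlation; without MJDtr-78Q library 2 the adjusted p was 0.227 and the median relative to all tested genes -0.17, against -0.56 without MJDtr-78Q library 1. The time of day at which heads were taken is not given in the sources used here.

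Sex-specific transcripts had a median of -0.16 over 12 members. The list pools transcripts of both sexes, among them yolk protein genes and roX1, so its median and calls give no direction for sex. Whether the groups differed in their share of males and females was not tested. Cyp4d21 fell by 1.48 (SE 0.28) and Obp99b by 1.40 (SE 0.28), both with adjusted p = 0.0279 over the list alone, and 0 passed over all genes. The gene sxe2 differed by -0.85 (SE 0.29). Camera gave adjusted p = 0.0129, with adjusted p = 0.737 with an estimated correlation, and this was the list that fry called (adjusted p = 0.0314). The camera call was lost without control library 1 (adjusted p = 0.0659) and without MJDtr-78Q library 2 (adjusted p = 0.0840), and the median relative to all tested genes ran from -0.29 without MJDtr-78Q library 1 to -0.10 without control library 1 (-0.23 without MJDtr-78Q library 2). The same median was -0.13 with all 4 libraries, -0.31 under both TMM and upper-quartile scaling and -0.21 after length correction.

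Cytosolic ribosomal protein genes had a median of -0.24, with 76 of 77 members below 0. None of the 77 passed adjusted over the list alone or over all genes, and camera gave adjusted p = 9.3e-04, with adjusted p = 0.895 with an estimated correlation. The direction turned with the library left out: relative to all tested genes, the median was -0.71 without MJDtr-78Q library 2 and 0.23 without MJDtr-78Q library 1, and the call was lost without control library 2 (-0.08, adjusted p = 0.284). It was -0.37 without control library 1, -0.21 with all 4 libraries and -0.13 after length correction.

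Markers of neurons and glia had medians of 0.17 (12 genes, camera adjusted p = 0.223) and 0.11 (17 genes, adjusted p = 0.89). Dendrite morphogenesis genes had a median of 0.18 (24 genes, adjusted p = 0.239), synaptic vesicle and active zone genes one of 0.12 (22 genes, adjusted p = 0.276), and ion channels one of 0.06 (30 genes, adjusted p = 0.28). Neurotransmitter synthesis and transport genes had a median of 0.11 (19 genes, adjusted p = 0.458), and genes of axon injury and neurodegeneration one of 0.06 (15 genes, adjusted p = 0.69). Autophagy genes had a median of 0.14 (22 genes, adjusted p = 0.302), antioxidant enzymes one of -0.04 (22 genes, adjusted p = 0.605), glutathione transferases one of -0.21 (29 genes, adjusted p = 0.383) and cytochrome P450 genes one of -0.13 (64 genes, adjusted p = 0.239). Insulin signalling and feeding response genes had a median of -0.12 (21 genes, adjusted p = 0.111). Mitochondrial ribosomal protein genes had a median of -0.11 (70 genes, adjusted p = 0.114), nuclear genes of oxidative phosphorylation one of -0.16 (41 genes, adjusted p = 0.111), the mitochondrial genome one of -0.0075 (12 genes, adjusted p = 0.948) and histone genes one of -0.07 (4 genes, adjusted p = 0.869). For the mitochondrial genome camera's direction was up, and relative to all tested genes the antioxidant median turned to above 0 with TMM and upper-quartile scaling. In each of these lists 0 members passed adjusted over the list alone or over all genes. Several of these medians changed sign with the library left out: that of synaptic vesicle genes was -0.33 without MJDtr-78Q library 1 and 0.60 without MJDtr-78Q library 2.

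The replicates of a group differed with gene length. In 5 equal groups of genes by exonic length, control 1 minus control 2 had medians from -0.35 in the shortest genes to 0.29 in the longest, and MJDtr-78Q 1 minus MJDtr-78Q 2 from -0.79 to 0.82. Spearman's rho with length, across 8641 genes that are not independent replicates, was 0.627 and 0.754. The group difference followed length less closely, with rho = 0.281 and medians from -0.16 to 0.12. When the length trend was removed from each library, a correction chosen after seeing the data, 6 genes passed (limma), 3 higher and 3 lower. Among them, trpl differed by -3.08 (adjusted p = 0.0153), and BomS4 and BomBc1, which encode immune-induced Bomanin peptides and of which BomS4 was singled out after its values were seen, by 2.70 and 3.06 (adjusted p = 0.0153 and 0.0292). The others were BomS2 (2.20, adjusted p = 0.0234), CG11426 (-1.86, adjusted p = 0.0234) and CG6656 (-2.21, adjusted p = 0.0436), the last 2 singled out after their values were seen.

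**Figure D4:**
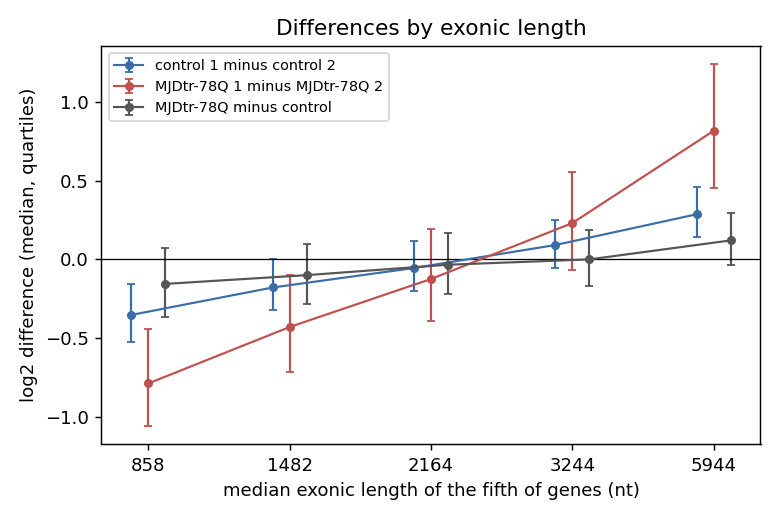
Median log2 difference in 5 equal groups of genes by exonic length, with bars from the lower to the upper quartile, for the replicate pairs and for the groups; the horizontal axis gives each group's median length in nt. The replicate differences rise from -0.79 to 0.82 for MJDtr-78Q and from -0.35 to 0.29 for control.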

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

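The choices were fixed before the data were examined, except the main scaling, exchanged with a listed alternative, and values with no scaling between groups and the 2 length corrections, which were chosen after seeing the data. A result counts as reversed below where its sign, or for a list the direction in camera, changed and its value or the alternative passed the threshold. The count of 0 genes and the 12 gene lists held under pseudocounts of 0.5 and 5, both filters, robust variance and no intensity trend, and 0 genes passed under TMM and upper-quartile scaling, where 13 lists passed. The COPII list passed under no alternative (median relative to all genes 0.03 to 0.32). edgeR and DESeq2 were not run, since the log2 values averaged within groups hold no whole reads.

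With the replicate number as a block, 387 genes passed (229 higher, 158 lower, 351 at least 2-fold) and 12 lists. The block leaves fewer residual degrees of freedom than the main fit, so its calls rest more on the variance shared across genes. The labels do not say that equal numbers share a batch, and with 2 pairs the correlation of replicate differences across genes (0.536, or 0.331 after length correction) does not settle pairing. With length correction 6 genes passed (3 higher, 3 lower, 6 at least 2-fold), and with the block as well 906 (481 higher, 425 lower, 388 at least 2-fold). In simulated data a straight-line length trend from these libraries took recovered 2-fold genes from a mean of 67.4 of 100 to 0.30. Length correction gave 66.5. All simulated genes had the same dispersion, 0.02, and the correction removes such a trend by construction. The recovery therefore does not show how many real changes the correction restores.

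Without scaling between groups the median of all tested genes was -1.23, and 6742 genes passed (14 higher, 6728 lower, 6191 at least 2-fold), with 6 lists, 4 of them among the 12 (proteasome, phototransduction, cuticle and muscle). The other 8 lost their call, among them heat-inducible heat shock genes (adjusted p 0.0665, median relative to all genes -0.78). Reversed there were Sec24CD (-0.85), Sec24AB (-0.97), Sec23 (-1.04), CG9175 (-1.19), Sec31 (-1.08), Sar1 (-1.10), trp (-0.89) and the camera direction of olfactory markers, whose median relative to all genes kept its sign (-0.55, adjusted p 0.764). All but the last follow the shift of all genes. With an estimated correlation 0 lists passed, in a test with few degrees of freedom.

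Leaving out 1 library gave 0 to 3 genes (0 to 3 higher, 0 lower, 0 to 3 at least 2-fold) and 11 to 24 lists, with 24 without MJDtr-78Q 2; a lone library is assumed to vary like the other group. The 3 genes, without control 1, were CG8483, CG34217 and frm, named after their values were seen, which differed between the 2 controls. Medians relative to all genes that reversed ranged from -0.46 to 0.21 for glutathione transferases, -0.33 to 0.60 for synaptic genes, -0.33 to 0.69 for ion channels, -0.71 to 0.23 for cytosolic ribosomal proteins, -0.47 to 0.26 for mitochondrial ribosomal proteins, -0.48 to 0.24 for oxidative phosphorylation, -0.67 to 1.29 for antimicrobial peptides and -0.32 to 0.37 for the mitochondrial genome. The cause was not tested.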

Other observations

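Among peptidoglycan recognition and immune effector genes, 2 rose and 2 fell adjusted over the list alone, and 0 of 27 passed over all genes. The Bomanin genes BomBc1 and BomS2, induced through the Toll pathway, rose by 2.91 (SE 0.58) and 2.03 (SE 0.43), and the related BomS4, singled out after its values were seen, differed by 2.52 (SE 0.53). The stress-induced Turandot genes TotX and TotA fell by 2.12 (SE 0.30) and 2.07 (SE 0.42). The list as a whole had a median of -0.28 (camera adjusted p = 0.0971). Antimicrobial peptides had a median of 0.26 over 13 genes (camera adjusted p = 0.273), and the cecropin gene CecC rose by 2.47 (SE 0.32), with adjusted p = 0.00856 over the list alone, while CecB differed by 2.13 (SE 0.72), or 1.17 without control library 1. Adjusted over that list alone 1 gene passed, and 0 over all genes. The antimicrobial median was 1.29 without MJDtr-78Q library 1 and -0.67 without MJDtr-78Q library 2.

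Apoptosis and JNK signalling genes had a median of 0.05 over 22 members (camera adjusted p = 0.223), with 0 past the threshold adjusted over the list alone or over all genes. The pro-apoptotic gene hid differed by 1.11 (SE 0.25). The caspase genes Dronc and Drice differed by 1.73 (SE 0.53) and 0.88 (SE 0.30), and the matrix protease gene Mmp1 by 1.40 (SE 0.52). Without control library 2 Dronc differed by 1.10 and Mmp1 by 0.67, and without control library 1 Mmp1 by 2.12. Fat body markers had a median of -0.07 over 19 members and 0 past the threshold on either adjustment (camera adjusted p = 0.715, mean 0.18 and direction up, with a median above 0 relative to all tested genes under TMM and upper-quartile scaling), although the larval serum protein gene Lsp1gamma and Fbp2 differed by 1.66 (SE 0.41) and 1.96 (SE 0.63), the latter by 1.11 without control library 2. Seminal fluid and testis proteins had 3 tested members with a median of 0.68 (camera adjusted p = 0.111), 1 of which passed adjusted over the list alone and 0 over all genes. That member, Acp1, which differed by 1.37 (SE 0.25), and Acp65Aa, which differed by 0.68 (SE 0.39) and sets the median, encode adult cuticle proteins and not seminal ones, so the list says little about seminal proteins. Acp65Aa differed by 0.24 without MJDtr-78Q library 2 and by 1.11 without MJDtr-78Q library 1. Among genes chosen after their values were seen, for size at an unadjusted p under 0.01, CG14770, CG42323, resilin, CG34375 and CG11345 were higher by 2.68, 2.48, 2.26, 2.23 and 2.20. In the same way CG6656, Crg-1, CG9676, SmydA-8 and CG8329 were lower, at -2.26, -2.21, -2.16, -1.93 and -1.93. None of these 10 passed over all genes, although CG6656 did after length correction (-2.21, adjusted p = 0.0436) and each of the 10 did with the replicate number as a block (highest adjusted p = 0.00187). The 10 were chosen for size from the same values, so this gives no separate support.

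The tests of library depth, gene length, fragment size, RNA breakage, scaling and eye tissue in this part were chosen after the results were seen. A first pattern is the length trend between replicates. Library depth as its cause is argued against: within 5 equal groups of genes by mean expression the lowest rho with length was still 0.422. Fragment size selection as its cause is also argued against, since the medians went on growing between the next-longest and the longest of the 5 length groups, by 0.20 in the control pair and 0.59 in the MJDtr-78Q pair, where transcripts are far longer than fragments. The same step of 0.20 is what RNA breakage before poly(A) selection would need. That prediction was only the reverse of the one for fragment size, so breakage faced no test of its own. Differing RNA integrity between libraries may be a source of the trend, a hypothesis that coverage along transcripts, not analysed here, would test. Other length-linked causes were not tested.

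A second pattern is the higher proteasome median. Transcript length as the whole cause is argued against, because the median after length correction was 0.968 (0.883 before). Scaling between the groups, by a factor per library or one that changes with expression, would move genes of equal expression alike, but in the deposited values with no scaling between groups the list's median lay 0.963 above the median of 10000 random lists matched by expression (-0.28 against -1.24, with random lists from -1.51 to -0.98). The members are correlated, so these lists give no p-value. A response to the polyglutamine protein may be behind the pattern, but the strain background and the transgene insertion are confounded with the group and were not tested.

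A further pattern is the lower phototransduction median. Transcript length as the whole cause is argued against by a median of -0.54 after length correction, and scaling by the median in the deposited values with no scaling between groups, which lay 0.475 below that of expression-matched random lists (-1.72 against -1.25, with the lowest random list at -1.45). A smaller share of eye tissue as the only cause would lower photoreceptor genes alike. The length-corrected members instead spread 5.05 times as widely as their median standard error, with 4 of 35 above 0 and 10 below -1. Members also expressed outside the eye, such as ninaD, add to that spread. The ratio was not taken for other genes, and its errors rest on 2 libraries per group, so its weight is limited. Loss of eye tissue may still contribute to part of the fall. Other tissue markers differed too, by camera with the preset correlation only. Medians were higher for cuticle (0.85), muscle (0.37) and hemocyte (0.43) genes and lower for olfactory and gustatory organs (-0.61). Relative to all tested genes the olfactory median was -0.08 without MJDtr-78Q library 1, and the hemocyte one 0.21 without control library 2. Shares of several tissues stay open. Strain background, including alleles of single photoreceptor genes such as trpl, stays open and was not tested.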
